A study of Arabidopsis thaliana with 10 samples.

How the data were processed

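RNA from pooled inflorescences was hybridised to 10 Affymetrix ATH1 arrays after biotin labelling of total RNA, per the labels' protocols. Plants grew in soil at 22 °C with 16 h of light and 8 h of dark. The deposited values are log2 intensities that the authors made with RMA, per the submitters' processing notes, which corrects background, normalizes between arrays and summarizes each probe set. The version of RMA is not stated. The values have 2 decimals, 1 column per array, and were used as deposited, with no further normalization. No label gives a batch, slide or scan date, so none could be tested.

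Of 22810 probe sets, 64 controls were left out and 22746 were tested. In the gene table used here, 13513 of these name 1 gene, 503 name several and 8730 are not listed and so are unnamed here, which does not mean that they have no gene. The table can be old. Names were used from probe sets with 1 gene only, and 13436 of these matched a locus in a RefSeq gene table (assembly TAIR10.1), which was used for names and for which genes lie next to each other. At the gene level the probe sets of a symbol were averaged, giving 13350 genes, and 6 symbols stand for more than 1 gene identifier, 0 of which is in a list or named.

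Groups were taken from the sample titles. Changes were tested with limma 3.58.1 in R 4.3.3, with 1 mean per group over all 10 arrays and moderated variances, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The comparison over both times used the mean of each line, 2 against 2. Comparisons with 0 min join induction, vapour and elapsed time, which includes the time of day, and mutant KLU was compared with uninduced plants of other lines. Gene lists with at least 3 measured members were tested with limma's camera at a preset correlation of 0.01 and at an estimated one, adjusted over the lists of a comparison. The design, the alternatives, the rule for named genes and 24 lists of 394 genes, of which 51 were measured, were fixed before the data were examined. The named genes are the 10 largest rises and falls past the threshold whose arrays do not overlap between groups, or the 5 with the smallest p where fewer than 3 probe sets pass, and up to 4 members of a list. The text names them in rank order and may name fewer.

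A further 22 lists were added later, chosen by symbol after the names were known and before any test was run, and a pollen marker score was added as a covariate after the first results were seen. After the results of these lists had been seen, the symbols of these lists were checked against the RefSeq table. CHI, there a chitinase, left the flavonoid list, and POR, there a tubulin-folding cofactor, left the nuclear photosynthesis list. The plastid genes rpl16, rps3 and rps4, missed at first, joined the plastid list. As first written, the plastid and flavonoid medians with wild-type KLU at 90 min were -0.55 and -0.66. The correction moved 1 list result across the threshold, the flavonoid list for mutant KLU at 240 against 90 min, from an adjusted p of 0.0506 to 0.0121. With an estimated correlation camera's adjusted p was 0.922, and among genes above the median level 0.0903. The median was -0.25, with -0.17 without the mutant array of line 3-2 at 240 min and -0.08 without that of line 1-5 at 90 min.

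The replicate labels name transformed lines that recur at each time of a construct, so the arrays are paired by line. The difference between the 2 lines correlated across probe sets between times, with 0.633, 0.475 and 0.606 for wild-type KLU and 0.348 for mutant KLU. Fits with the line as a fixed block (within a construct) or a random block with a correlation of 0.271 (between constructs) are given where they change a call or a count. Camera takes no random block, so its comparisons between constructs are unblocked.

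The fit was tested on simulated data with 200 changed probe sets per run in 10 runs over 22746 probe sets. For wild-type against mutant KLU at 240 min it recovered 31.2% of changes of 1 log2 unit and 88.1% of changes of 2, and for wild-type KLU at 240 min against uninduced 32.6% and 87.2%. Changes of 0.5 log2 units were recovered in 0.28% and 0.71%, in the same order. It called 0.02% of unchanged probe sets in each. The simulated noise was independent between arrays and genes, without line differences, so these rates may not hold for the real arrays. Comparisons that share arrays were set beside 100 simulated draws of unchanged groups, also without line differences. Other alternatives were a fit of the compared groups alone, trended and robust variances, probe sets above the median level, quantile normalization, median centring, a change of at least 2-fold and leaving out each array. Figures were drawn with matplotlib 3.10.9.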

Results

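The arrays measured transcripts in inflorescences of Arabidopsis thaliana, pooled with their young buds. The plants carried the klu-2 allele and a transgene that ethanol vapour switches on. The transgene encoded either wild-type KLU (CYP78A5), a cytochrome P450, or a mutant form of the protein that the series design uses as a control. The 10 arrays form 5 groups of 2 arrays. Wild-type KLU was sampled at 0, 90 and 240 min, and mutant KLU at 90 and 240 min. Each construct was represented by 2 independently transformed lines, 3-1 and 4-3 for wild-type KLU and 1-5 and 3-2 for mutant KLU. Every array gave values for 22810 probe sets, and the array medians lay between 5.93 and 6.05 on the log2 scale. The number of arrays limits the precision of every value. The KLU transcript itself was not analysed here, because the gene table used here names no probe set after it. Of the CYP78A family, CYP78A9 alone was measured under its name.

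The first principal component held 32.2% of the variance and ordered the wild-type KLU arrays by time. The second held 28.3% and separated the 2 lines of each construct at every time. It was 45.9 and -37.8 for wild-type lines 3-1 and 4-3 at 90 min, and 23.3 and -18.4 for mutant lines 3-2 and 1-5. In each group the line with the higher value also had the higher pollen marker score, as with 7.71 and 4.36, and 6.67 and 5.64, in the same order. So a line difference and the pollen share of the pooled tissue cannot be told apart on this component. The mutant KLU arrays lay between the uninduced and the induced wild-type KLU arrays on the first component, line 3-2 at -4.20 and 0.10 and line 1-5 at -21.8 and -18.4.

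**Figure D1:**
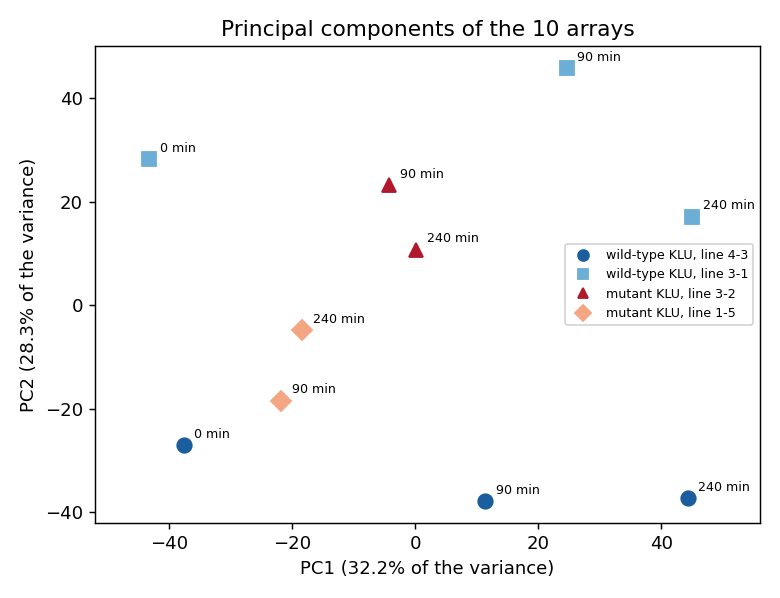
First and second principal components of the 10 arrays (axes in log2 units, with the share of the variance). Each point is 1 array, its marker shows the construct and line and its label the time, and the uninduced arrays lie at -43.3 and -37.7 on the first component while the wild-type KLU arrays at 240 min lie at 45.0 and 44.3.

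The comparison of wild-type with mutant KLU at 240 min asks which transcripts respond to the active enzyme, since both groups had the same vapour and the same elapsed time. The constructs were carried by different lines, and no uninduced mutant array exists. A line difference or an unequal level of the transgenes is therefore not excluded. With wild-type KLU, transcripts of CSLA01, which encodes a cellulose synthase-like glucomannan synthase, and of BSMT1, which encodes a benzoic and salicylic acid methyltransferase, were lower. Transcripts of TUA1, an alpha-tubulin gene known from pollen, and of UGT71C3, a UDP-glycosyltransferase gene, were higher. In limma's moderated test, 164 probe sets rose and 94 fell with wild-type KLU, and among probe sets above the median level 100 rose and 101 fell. A fit of the 2 compared groups alone, with fewer arrays to estimate the spread, called 0. The largest rises among named genes were AT1G29180 (log2 difference 4.31, SE 0.585, adjusted p = 0.023), AT1G01390 (4.28), AT4G29640 (3.85), AT3G62730 (3.79, adjusted p = 0.00622), AT3G62780 (3.75), AT3G12440 (3.61), AT1G80140 (3.51), AT5G61550 (3.40), AT1G12130 (3.37) and AT4G29600 (3.15). The largest falls were CSLA01 (log2 difference -2.60, SE 0.209, adjusted p = 0.00832), AT5G55720 (-2.59), AT4G24140 (-1.98), AT1G60590 (-1.97), AT5G01075 (-1.89), IQD19 (-1.86), BSMT1 (-1.86), AT1G54820 (-1.75), AT2G18890 (-1.72) and AT5G19340 (-1.67). At the gene level TUA1 rose by 1.61 (SE 0.169) and UGT71C3 by 2.79 (SE 0.301), each with an adjusted p of 0.0091. Both arrays of each group lay apart for each of these genes, as for CSLA01 with 5.77 ± 0.30 under wild-type and 8.37 ± 0.18 under mutant KLU (SD, 2 arrays each). The count depended on single arrays. It was 15 without the mutant array of line 1-5 at 240 min, 20 without that of line 3-2, 74 without the wild-type array of line 3-1 at 240 min, 4 without that of line 4-3, and 143 without either uninduced array. Of 21 named genes past the threshold here, 1, AT3G62730, stayed past it without each of the 10 arrays in turn. TUA1 and UGT71C3, named as list members, are not among these 21 and were not put to this check. CSLA01 had an adjusted p of 0.0514 without the mutant array of line 3-2 at 240 min and 0.0605 without the wild-type array of line 4-3 at 240 min. BSMT1 had 0.114 without the mutant array of line 1-5 at 240 min and 0.0595 and 0.0766 without those same 2 arrays.

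Against both controls, the mutant protein at 240 min and the uninduced wild-type lines, 161 probe sets rose and 84 fell with wild-type KLU at 240 min, and 99 rose and 93 fell among probe sets above the median level. Fits of the compared groups alone, with fewer arrays to estimate the spread, left 0. The genes with the largest mean change were AT1G29180, AT3G62780, AT1G01390 and AT3G12440 among the rises, and CSLA01, AT5G55720, AT1G60590, BSMT1, AT4G24140 and TBL26 among the falls. Over these 161 probe sets the array medians were 7.57 and 7.74 with wild-type KLU at 240 min, 7.26 and 7.47 with it at 90 min, 5.33 and 5.62 with mutant KLU at 240 min, and 5.23 and 5.15 in the uninduced lines. The probe sets were chosen for these differences at 240 min, so the medians at 240 and 0 min describe the choice. The arrays at 90 min come from the same lines, so they are not independent of it. The comparisons share the wild-type KLU arrays at 240 min. Unchanged groups simulated with the same sharing gave 0 such probe sets in each of 100 draws. With no changes and no line differences in that simulation, few calls could arise, so its count cannot show a response. Independent lists of the observed sizes would share 6.02 rises and 2.96 falls. The correlation of the 2 sets of changes across probe sets, which are not independent replicates, was 0.757 against 0.498 simulated, and the covariance was 0.190 against 0.0417. Part of the excess overlap may come from the shared arrays, which are too few to split. Without 1 array the count of 245 fell to 4 (wild-type line 4-3 at 240 min), 72 (wild-type line 3-1 at 240 min), 8 (mutant line 1-5 at 240 min), 19 (mutant line 3-2 at 240 min), 78 (uninduced line 3-1) and 128 (uninduced line 4-3).

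**Figure D2:**
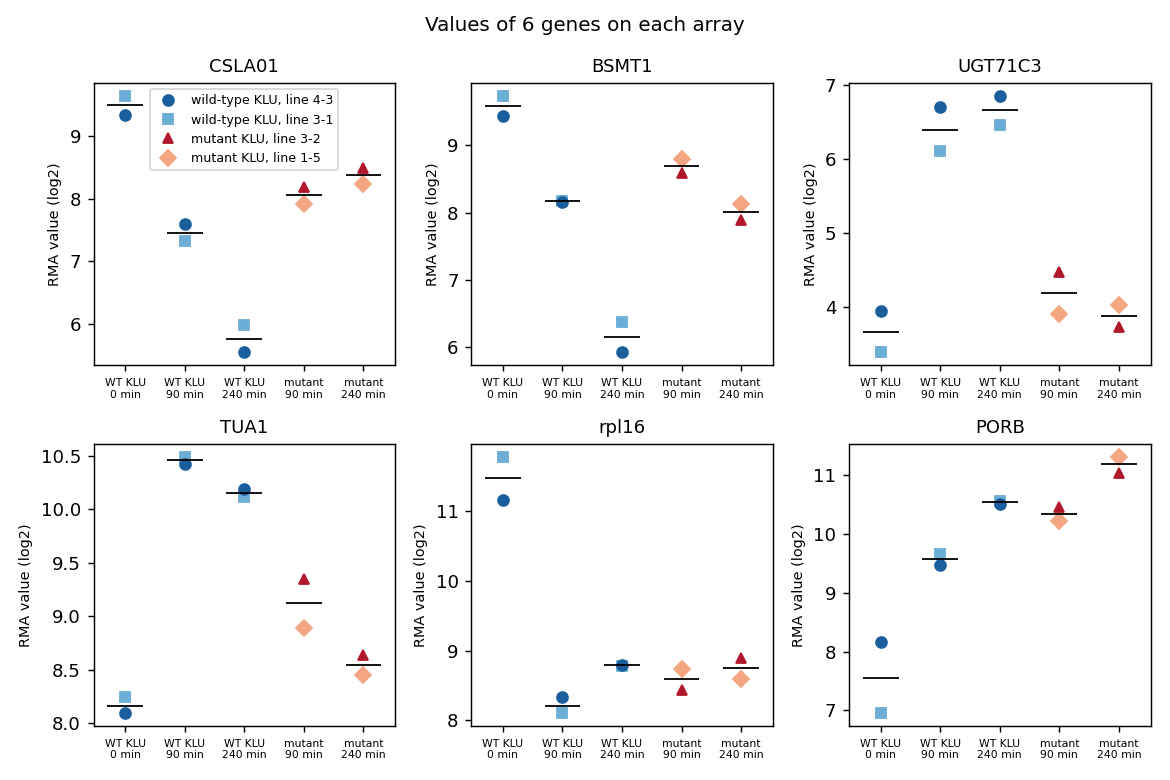
RMA values (log2) of CSLA01, BSMT1, UGT71C3, TUA1, rpl16 and PORB on each of the 10 arrays, by construct and time, with the group means as lines. CSLA01 has group means of 9.49, 7.46 and 5.77 at 0, 90 and 240 min with wild-type KLU and of 8.05 and 8.37 with mutant KLU.

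At 90 min the same comparison, with the same limits, asks which transcripts respond early to the active enzyme. In limma's test 1 probe set, 248692_s_at, passed, higher with wild-type KLU by 2.42 (SE 0.176, adjusted p = 0.0284), and 1334 had an unadjusted p under 0.05. It is unnamed here and was chosen after its value was seen. The named genes with the smallest p were AT3G55840 (log2 difference 2.32), AT1G20030 (1.62), AT3G12440 (2.85), AT5G25210 (-1.09) and AT3G57220 (1.24), none past the threshold, each with an adjusted p of 0.0601. With the line as a random block 12 probe sets rose and 1 fell, and all 5 of these genes passed, AT3G55840 with an adjusted p of 0.0387. At the gene level CYP78A9 differed by 1.19 (adjusted p = 0.0681), and the block brought this to 0.0465. The count was 48 without the mutant array of line 3-2 at 90 min and 4 without the wild-type array of line 3-1 at 90 min. It was 0 without the mutant array of line 1-5 at 90 min, without either wild-type array at 240 min and without either uninduced array. The 1 probe set also passed against the uninduced lines, and it is the 1 probe set changed against both controls at 90 min, with 12 under the block.

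Whether the difference between the constructs changed from 90 to 240 min was tested as an interaction, and limma called 0 probe sets, with 603 at an unadjusted p under 0.05. The genes with the smallest p were AT3G62730 (2.69), CSLA01 (-2.01), AT5G14580 (1.48), AT1G15480 (1.09) and AT3G14510 (1.21), each with an adjusted p of 1. So the larger number of calls at 240 than at 90 min was not shown to reflect a different response. The interaction gave 2 calls without the mutant array of line 1-5 at 240 min. Averaged over both times for each line, wild-type and mutant KLU differed in 0 probe sets in limma's test of 2 lines against 2, with 2209 at an unadjusted p under 0.05. The smallest p belonged to AT4G29600 (2.46), AT1G30740 (1.82), AT3G62730 (2.45), AT1G12130 (2.88) and AT4G29620 (2.28), all at an adjusted p of 0.178. With the 8 induced arrays kept apart and the line as a random block, 233 probe sets rose and 58 fell. In that fit AT4G29600, AT1G30740, AT1G12130 and AT4G29620 passed while AT3G62730 had an adjusted p of 0.174. It takes both times of a line as partly separate replicates, with 1 correlation of 0.271 for all probe sets. The line is the replicate, so these calls overstate the evidence from 2 lines against 2.

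Wild-type KLU at 90 min against the same lines at 0 min shows induction, ethanol vapour and 90 min of elapsed time together. PDC2, which encodes a pyruvate decarboxylase, rose, as did TUA1 and CYP78A9, a close relative of KLU. Transcripts of the plastid ribosomal protein genes rpl16, rpl14 and rpl20 fell, and so did the expansin gene EXPB3 and JMT, which encodes a jasmonate methyltransferase. In limma's test 252 probe sets rose and 117 fell, and 464 rose and 314 fell with the line as a block. The largest rises among named genes were AT3G63360 (log2 change 6.01, SE 1.05, adjusted p = 0.0412), AT1G29180 (4.66), AT3G62780 (4.56), AT4G29780 (adjusted p = 0.0413) and AT2G32190 (4.22). The largest falls were rpl16 (-3.26, SE 0.229, adjusted p = 0.00558), rpl14 (-2.85, adjusted p = 0.00168), AT3G14395 (-2.85), AT1G60590 (-2.80), rpl20 (-2.72), AT1G23205 (-2.32) and CSLA01 (-2.03). At the gene level the changes were 2.29 for TUA1, 2.70 for PDC2, 1.08 for CYP78A9, 2.02 for the protochlorophyllide reductase gene PORB, 1.77 for AGL30, -1.25 for JMT and -1.99 for EXPB3. TUA1 and AGL30 belong to a list of 22 pollen genes, of which these 2 passed over all genes and adjusted over the list alone. Its median was 0.26 (adjusted p = 0.0284, 0.888 with an estimated correlation, and 0.205 among genes above the median level), -0.28 without the array of line 3-1 at 90 min (adjusted p = 0.67), 1.03 without that of line 4-3, and 0.61 and 0.06 without the uninduced arrays of lines 3-1 and 4-3 (adjusted p = 0.00217 and 0.411). A score of 5 pollen markers was 6.17 at 0 min and 7.71 at 90 min in line 3-1, and 4.51 and 4.36 in line 4-3. The count of 369 was 57 without the wild-type array of line 3-1 at 90 min, 23 without that of line 4-3, 4 without the uninduced array of line 3-1, 6 without that of line 4-3 and 221 without either mutant array at 240 min. Of 20 named genes past the threshold, rpl14, rpl16 and rpl20 stayed past it without each array in turn. CSLA01 had an adjusted p of 0.0511 and 0.0579 without the arrays of lines 3-1 and 4-3 at 90 min, and 0.0938 and 0.0768 without those at 0 min.

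Wild-type KLU at 240 min against the uninduced lines gave the largest number of calls, again for induction, vapour and elapsed time together. The largest falls were CSLA01 (-3.73, SE 0.209, adjusted p = 0.00144), AT3G14395 (-3.55), BSMT1 (-3.44, SE 0.194, adjusted p = 0.00144), AT1G60590 (-3.35), AT1G48100 (adjusted p = 0.0402), AT5G55720 (-2.98) and GH9B8 (-2.97), a glycosyl hydrolase family 9 gene. The flavonol glycosyltransferase genes UGT78D1 (-1.69) and UGT78D2 (-1.30) fell, as did the expansin genes EXPA15 (-2.05), EXPB3 (-1.78) and EXPB1 (-1.17), while the expansin gene EXPA20 rose by 3.64. NGA1 (-1.20) and NGA4 (-0.74), genes of the NGATHA regulators of gynoecium and lateral organ growth, and the sugar transporter gene SWEET1 (-1.48) fell. PORB (2.99), PDC2 (2.56), UGT71C3 (3.00), TUA1 (1.99) and AGL30 (1.73) rose, and JMT fell by 2.05. In limma's test 835 probe sets rose and 716 fell, 1294 rose and 1395 fell with the line as a block, and 698 rose and 718 fell among probe sets above the median level. The largest rises among named genes were AT3G63360 (6.77), AGL86 (6.10, SE 1.43, adjusted p = 0.048), AT1G29180 (4.83), APS4 (4.81), AT3G62780 (4.67) and SBTI1.1 (4.63). The count of 1551 was 442 without the wild-type array of line 3-1 at 240 min, 372 without that of line 4-3 and 176 without the uninduced array of line 3-1. Of 34 named genes past the threshold, 16 stayed past it without each array in turn, among them CSLA01, BSMT1, AT3G62730, IQD19, TBL26, rpl14 and rpl16.

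Between 90 and 240 min with wild-type KLU limma called 0 probe sets, with 2313 at an unadjusted p under 0.05. The named genes with the smallest p were BSMT1 (-2.02), AT3G62730 (2.26) and AT1G71060 (1.25), each with an adjusted p of 0.124, then AT2G17850 (-2.63) and CSLA01 (-1.70). Without the wild-type array of line 4-3 at 90 min 1 probe set passed. Between 90 and 240 min with mutant KLU limma also called 0, with 490 at an unadjusted p under 0.05, and AT1G29660 (-1.96, adjusted p = 1) had the smallest p of the named genes. Without the mutant array of line 1-5 at 240 min 5 probe sets passed.

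Mutant KLU was set against the uninduced wild-type KLU lines to show what vapour and elapsed time did without the active enzyme, although these are different lines. At 90 min 4 probe sets rose and 5 fell in limma's test. AT3G15450 (2.53, SE 0.243, adjusted p = 0.0314) and AT5G25210 (1.44, adjusted p = 0.0185) rose, and rpl16 (-2.89, adjusted p = 0.018), rpl14 (-2.66) and rpl20 (-2.45) fell. The count of 9 was 0 without either mutant array at 90 min, 2 without either mutant array at 240 min, 5 without either wild-type array at 90 min, 4 without either wild-type array at 240 min, 1 without the uninduced array of line 3-1 and 3 without that of line 4-3. At 240 min 18 probe sets rose and 17 fell. PORB (3.63, SE 0.344, adjusted p = 0.0215), AT3G10020 (adjusted p = 0.0309), AT1G25275 (2.63), AT3G59350 (2.21), AT3G15450 (2.21), AT3G51450 (1.56), AT5G25210 (1.55) and CHL (adjusted p = 0.0423) rose. With the line as a random block CHL had an adjusted p of 0.0538. The falls were rpl16 (-2.73), rpl20 (-2.42), rpl14 (-2.39), BSMT1 (-1.58), AT5G15950 (-1.57), JMT (-1.41) and AT1G73600 (-1.33). The count of 35 was 10 without either mutant array at 90 min, 15 without the mutant array of line 1-5 at 240 min, 0 without that of line 3-2, 21 without either wild-type array at 240 min, 8 without the uninduced array of line 3-1 and 5 without that of line 4-3.

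The changes against the uninduced lines ran in parallel for the 2 constructs, with the uninduced arrays in common. At 240 min 16 probe sets rose and 17 fell in both, against 0.66 and 0.54 for independent lists, and simulated unchanged groups shared at most 1. The simulated groups had no changes and no line differences, so they could share few calls, and their correlations leave out the pairing by line. The correlation across probe sets was 0.676 against 0.5 simulated, and the covariance was 0.151 against 0.0419, a difference of 0.109. At 90 min 3 rose and 5 fell in both, with a correlation of 0.692 against 0.501 and a covariance of 0.110 against 0.0419, a difference of 0.0683. The uninduced arrays are too few to split, so part of the excess overlap may come from sharing them.

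Plastid-encoded transcripts were lower on the induced arrays of both constructs than on the uninduced ones. Over 69 such genes the median log2 change was -0.55 at 90 min and -0.39 at 240 min with wild-type KLU, and -0.26 and -0.39 with mutant KLU. With wild-type KLU at 90 min 13 of them fell over all genes and 27 fell and 1 rose adjusted over the list alone, among them rpl14, rpl20, rpl16 and psaB. At 240 min 15 fell and 1 rose over all genes, and 20 fell and 3 rose adjusted over the list alone. With mutant KLU 4 and 3 fell over all genes, and adjusted over the list alone 22 fell at each time while 1 and 3 rose. The camera test with a preset correlation called the list in these 4 comparisons, with adjusted p of 2.61e-13, 6.87e-05, 1.39e-09 and 8.2e-09. With an estimated correlation the adjusted p were 0.43, 0.469, 0.344 and 0.482. The preset calls stayed without each array in turn, but the medians themselves moved by over 1.5 times. With wild-type KLU they were -0.26 at 90 min without the array of line 3-1 at 90 min and -0.24 at 240 min without that of line 3-1 at 240 min. With mutant KLU at 90 min the median was -0.52 without the array of line 1-5 at 90 min, -0.16 without that of line 3-2, and -0.43 and -0.15 without the uninduced arrays of lines 3-1 and 4-3. With mutant KLU at 240 min it was -0.25 without the array of line 3-2 at 240 min or without the uninduced array of line 4-3. Between the constructs the plastid median was -0.18 at 90 min with wild-type against mutant KLU (adjusted p = 0.000309, and 0.909 with an estimated correlation) and 0.00 at 240 min (adjusted p = 0.889). At 90 min it was -0.02 without the wild-type array of line 3-1 (adjusted p = 0.24), -0.32 without that of line 4-3, -0.09 without the mutant array of line 1-5 (adjusted p = 0.246) and -0.26 without that of line 3-2. For the interaction it was 0.20 (adjusted p = 0.0128, 0.752 with an estimated correlation, and 0.0531 among genes above the median level). That call ended without the arrays at 90 min of mutant line 1-5 (median 0.10, adjusted p = 0.44) or wild-type line 3-1 (0.05, 0.216), or those at 240 min of mutant line 1-5 (0.18, 0.104) or wild-type line 4-3 (0.12, 0.0617). The interaction median was 0.33 and 0.30 without the arrays of mutant line 3-2 and wild-type line 4-3 at 90 min. Over 16 mitochondrion-encoded genes the medians were -0.22, -0.14, -0.42 and -0.50 in the same order, with preset adjusted p of 0.00776, 0.0538 (not past the threshold), 5.89e-07 and 4.94e-07, and 0.511, 0.469, 0.344 and 0.208 with an estimated correlation. The first of these calls ended without the wild-type array of line 4-3 at 90 min, with a median of -0.07 and an adjusted p of 0.168. The last median was -0.30 without the mutant array of line 1-5 at 240 min. Each of the 2 medians kept its sign under quantile normalization and median centring where the list was called. These scalings moved no array median by more than 0.074, so they could change little.

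Flavonoid synthesis genes were lower in the same 4 comparisons, with medians over 8 genes of -0.78 and -1.05 with wild-type KLU at 90 and 240 min and -0.67 and -0.82 with mutant KLU. UGT78D2 fell at both times with wild-type KLU, and UGT78D1 and CHIL (-2.38) fell at 240 min. With wild-type KLU 1 and 3 of the 8 fell over all genes and 5 and 5 adjusted over the list alone, and with mutant KLU 0 over all genes in limma's test and 4 and 7 adjusted over the list alone. The preset adjusted p were 1.3e-05, 0.000106, 6.24e-06 and 9.62e-09, and with an estimated correlation 0.43, 0.469, 0.344 and 0.208. Without each array in turn these calls stayed, although without the uninduced array of line 4-3 the medians at 90 min were -0.48 with wild-type and -0.42 with mutant KLU, and quantile normalization and median centring left the medians below 0. These scalings moved array medians by at most 0.074, so a change of sign was hardly possible. A list of 39 floral and organ development genes was lower with wild-type than with mutant KLU at 240 min, with a median of -0.23 and 31 of 39 genes lower, 0 past limma's test over all genes and 1 adjusted over the list alone. Its preset adjusted p was 0.000554, 0.563 with an estimated correlation, and 0.14 among genes above the median level. Against the uninduced lines its median was -0.24 at 240 min (adjusted p = 0.00342, 0.469 with an estimated correlation, and 0.172 among genes above the median level), and NGA1 and NGA4 fell. Without the wild-type array of line 3-1 at 240 min that median was -0.15. Among 32 nuclear photosynthesis genes the median was -0.18 with wild-type against mutant KLU at 90 min (adjusted p = 2.02e-05, and 0.909 with an estimated correlation), with 0 past limma's test over all genes. Without the wild-type array of line 3-1 at 90 min it was -0.08 (adjusted p = 0.167), and -0.29 without that of line 4-3. The same list was higher at 240 than at 90 min with wild-type KLU (median 0.21, adjusted p = 0.00019, and 0.495 with an estimated correlation) and with mutant KLU (median 0.13, adjusted p = 0.000352, and 0.922). Both of these calls stayed without each array in turn, and the first median was 0.35 without the wild-type array of line 4-3 at 90 min. With mutant KLU at 240 min against the uninduced lines its median was 0.16 (adjusted p = 0.000112, and 0.593 with an estimated correlation), 0.04 without the uninduced array of line 3-1 (adjusted p = 0.18) and 0.30 without that of line 4-3. With wild-type KLU at 90 min against them it was -0.17 (adjusted p = 0.0275, 0.888 with an estimated correlation, 0.187 among genes above the median level and 0.0508 after quantile normalization), -0.26 and -0.01 without the uninduced arrays of lines 3-1 and 4-3 (adjusted p = 8.3e-05 and 0.99) and -0.07 without the array of line 3-1 at 90 min (adjusted p = 0.489).

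Of the 24 lists of genes fixed before the data were examined, 9 had at least 3 measured members. The preset camera test called 4 results among them, and 0 held with an estimated correlation. The hypoxia and ethanol metabolism list of PDC2, AT4G17260 and ACS was higher with mutant KLU than in the uninduced lines at 90 min (median 0.54, adjusted p = 0.0347, and 0.298 with an estimated correlation) and at 240 min (median 0.14, adjusted p = 0.0498, and 0.363). Among genes above the median level these adjusted p were 0.0525 and 0.169. For wild-type KLU at 90 min its adjusted p was 0.0591, and 0.0354 with the line as a block, with PDC2 past the test over all genes and adjusted over the list alone. The gibberellin receptor genes GID1A, GID1B and GID1C (median 0.39) and 3 heat shock genes (median 2.01) were called for mutant KLU at 240 min against the uninduced lines, each with an adjusted p of 0.0498, and 0.363 with an estimated correlation. Over all genes 0 of the 3 members passed in either list, and adjusted over the list alone 1 gibberellin gene and 0 heat shock genes rose. The hypoxia call at 90 min ended without the mutant array of line 3-2 at 90 min or either uninduced array, with an adjusted p of up to 0.363, and its median was 0.35 without the mutant array of line 1-5 at 90 min and 0.34 without the uninduced array of line 3-1. The hypoxia call at 240 min stayed without the mutant array of line 3-2 at 240 min alone, with a median of 0.46. Without the mutant array of line 1-5 at 240 min its median was -0.07, and 0.28 without the uninduced array of line 4-3. In contrast, the gibberellin and heat shock calls stayed without the mutant array of line 1-5 at 240 min alone. After quantile normalization these 3 calls at 240 min had adjusted p of 0.0873 or 0.0908. The heat shock median was 4.51 without the mutant array of line 1-5 at 240 min and -0.10 without that of line 3-2, where the gibberellin median was 0.24. For mutant KLU at 240 against 90 min the heat shock list had an adjusted p of 0.098, and 0.02 with the line as a block. The 3 reference genes measured changed by -0.20 to 0.18 over all comparisons, with no adjusted p under 0.558.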

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

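The pollen covariate, leaving out each line and the alternatives of the later lists were chosen after the data were seen, and the other alternatives before. Of the genes ranked by a comparison, none changed direction under an alternative that included it. They had been picked for large changes or small p, so a reversal was hardly possible. Genes named only as list members, such as TUA1 and UGT71C3, were run with the line as a block but through none of the other alternatives. With the line as a replicate block the counts were 13 for wild-type against mutant KLU at 90 min, 778 and 2689 for wild-type KLU at 90 and 240 min against uninduced, 291 over both times and 12 against both controls at 90 min. The 291 takes both times of a line as partly separate replicates. The block gave counts within 1.5 times for the other comparisons. It added 9 calls of the later lists, among them autophagy in wild-type KLU at 240 min against uninduced (adjusted p = 0.0104), and 2 of the fixed lists. In a fit of the compared groups alone the counts were 0 for wild-type against mutant KLU at 90 and at 240 min, 59 and 424 for wild-type KLU against uninduced, 0 and 19 for mutant KLU against uninduced, and 0 against both controls at either time, with fewer arrays to estimate the spread. Trended and robust variances gave 13 for wild-type against mutant KLU at 90 min, 21 for mutant KLU at 90 min and 13 against both controls at 90 min. Probe sets above the median level gave 0, 22 and 0 for these and 1 fixed list. Quantile normalization gave 0 and median centring 4 for wild-type against mutant KLU at 90 min and likewise against both controls, and no scaling moved an array median by more than 0.074. A minimum of 2-fold left 990 for wild-type KLU at 240 min. With the pollen covariate the counts were 127 and 754 for wild-type against mutant KLU at 90 and 240 min, 883 and 3032 for wild-type KLU against uninduced, 1 between its times, 140 and 287 for mutant KLU, and 114 and 673 against both controls. With an estimated correlation 0 of 4 fixed and 0 of 42 later list results held. The cause was not tested for these changes, except that fewer arrays enter the fit of the compared groups.

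Without each array in turn the counts ranged from 0 to 48 for wild-type against mutant KLU at 90 min, 4 to 219 at 240 min, 4 to 266 and 176 to 1545 for wild-type KLU at 90 and 240 min against uninduced, 0 to 1 between its times, 0 to 5 between the times of mutant KLU, 0 to 5 and 0 to 27 for mutant KLU against uninduced, 0 to 2 for the interaction, 0 to 0 over both times (also without each line), 0 to 48 and 4 to 207 against both controls at 90 and 240 min, 0 to 8 for the fixed lists and 41 to 59 for the later ones. The array left alone in a group was assumed to vary like the other groups. The alternatives for the KLU transcript were not run, because it has no named probe set here.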

Other observations

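Of the tests below, those of a standing line difference, of the pollen marker levels, of organelle transcripts as a class, of 1 uninduced array for mutant KLU and of chance placement were chosen after the result was seen, as was the comparison of single arrays.

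For the 258 probe sets that differed between wild-type and mutant KLU at 240 min, a standing difference between the transformed lines should also appear between the uninduced wild-type lines and the mutant lines at 240 min. The median share of the difference present there was -4.0% (quartiles -19.6% and 8.26%). No uninduced mutant array exists, so this share also holds 240 min of vapour and elapsed time in the mutant lines. A standing difference that these offset is not excluded. A higher pollen share with wild-type KLU would raise pollen markers with the probe sets that rose, but 5 markers were lower by 0.32 on average (-0.55 to -0.10), against a smallest rise of 0.72, and in the list of 22 pollen genes 15 were lower (median -0.11) while TUA1 and AGL30 went the other way, by 1.61 and 1.34 (adjusted p = 0.0091 and 0.0582). With their score as a covariate 258 of 258 calls stayed, but this could remove little, since the score differed more between the wild-type lines (2.41) than between constructs. The 84 probe sets that fell against both controls did not follow the score. In wild-type lines 3-1 and 4-3 at 240 min their medians were 6.42 and 6.53, with scores of 6.85 and 4.44. At 0 min they were 8.04 and 7.97, with scores of 6.17 and 4.51. In mutant lines 1-5 and 3-2 at 240 min they were 8.04 and 7.82, with scores of 5.83 and 6.09. But the fit that picked these 84 favours probe sets whose 2 arrays in a group lie close together. The score differed widely within the wild-type groups, so probe sets that follow it were unlikely to be picked. This check therefore cannot decide on a lower pollen share, and older buds stay open too. On the arrays at 90 min the 161 probe sets that rose against both controls had medians of 7.26 and 7.47 in the wild-type lines. In the mutant lines the medians were 5.41 and 5.97. These arrays come from the same lines and entered the variances of the picking fit, so they are no independent check. A response to the active enzyme stays open, as does an unequal level of the transgenes, whose transcript was not analysed here.

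Plastid-encoded transcripts were lower on the induced arrays of both constructs. With wild-type KLU a single high uninduced array would bring the median change at 90 min near 0 when left out, where it was -0.45 without uninduced line 4-3 and -0.62 without uninduced line 3-1, while the induced array of line 3-1 moved it more, to -0.26 when left out. With mutant KLU this stays open, since without uninduced line 4-3 the medians were -0.15 at 90 min and -0.25 at 240 min, from -0.26 and -0.39. A loss of organelle transcripts as a class, as from RNA quality or priming, cannot be told apart from a plastid effect. At 240 min with wild-type KLU the mitochondrion-encoded median lay 0.25 above the plastid-encoded one, under the 0.36 that marks the upper end of 10000 random splits. This difference was 0.33 at 90 min with wild-type KLU. With mutant KLU it was -0.16 at 90 min and -0.10 at 240 min, where the mitochondrion-encoded median was the lower one. Vapour, elapsed time and time of day stay open, since every uninduced array is from 0 min.

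Genes that rose with wild-type KLU at 240 min against both controls lay next to each other along the chromosomes more often than random genes did. Of 95 such genes with a locus, 12 had another within 3 loci, against a mean of 1.54 in 10000 random draws (permutation p = 0.0002), among them AT4G29580, AT4G29600, AT4G29620, AT4G29630 and AT4G29640. Of the 43 that fell, 0 did (permutation p = 1). As many genes picked by the difference between the uninduced lines gave 11, so a clustering common to genes that vary on these arrays cannot be told apart from a response to KLU. Probe sets shared between near-identical copies also stay open, since by their suffix 0 of the 12 clustered genes and 1 of the others were shared (Fisher's exact test, two-sided, p = 1).

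On 1 array, mutant line 3-2 at 240 min, 17 probe sets lay more than 2 log2 units above every other array, against 0 to 2 on each of the others. At 1 log2 unit other arrays stood apart more, with 86 probe sets on wild-type line 3-1 at 90 min, 53 on wild-type line 4-3 at 240 min and 41 on uninduced line 3-1, against 27 on this array. The 17 include AT1G53540 (8.27, against 3.05 to 3.34 elsewhere), AT2G29500 (8.34, against 2.75 to 4.43), ATHSP22.0 (7.51, against 3.80 to 4.55) and AT5G48570 (9.49, against 4.36 to 7.29). AT1G53540 and AT5G48570 belong to the heat shock list called above for mutant KLU at 240 min, whose median of 2.01 was -0.10 without this array. The array is also 1 of the 2 mutant arrays in the comparison of the constructs at 240 min. The mutant lines also differed in AGL86, with 7.40 and 7.57 in line 3-2 and 2.95 and 4.33 in line 1-5 at 90 and 240 min, against 3.18 and 3.33 in the uninduced lines.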
